A study of Drosophila melanogaster with 2 samples.

How the data were processed

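Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole wandering larvae of Drosophila melanogaster, males and females pooled, that carried a fusion of the transcription factor Eyeless to enhanced green fluorescent protein (ey-eGFP). Per the labels' description, the fusion protein was pulled down with an antibody against GFP, while their antibody entry reads ey, and the description was followed here. Per the labels, the chromatin was sheared by sonication, and the stated size range was 200 to 800 bp. The labels number the biological replicates 1 and 3. They form 1 group, so no comparison between conditions was possible and each statement about spread rests on 2 libraries.

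For each replicate the authors deposited a list of called regions meant as input to an irreproducible discovery rate (IDR) procedure, which therefore holds weak as well as strong regions. For both replicates together they deposited such a list called on the pooled alignments and an IDR-thresholded list termed optimal, all in the genome builds dm6 and dm3. Per the file headers and the listings that came with them, each list was derived from alignments and a control alignment, and the optimal list from the lists of both replicates and of the pool. The aligner, the peak caller and the IDR threshold are not given in the sources used here, and the control was not analysed here. The deposited signal of a region is the authors' own strength value, whose scale is not stated. It was used only to rank, filter and describe regions within a list, and to correlate the replicates, and no signal level was compared between lists. The deposited −log10 q-value reached a ceiling in 36.9% of replicate 1 regions, 21.2% of replicate 3 regions, 26.9% of pooled regions and 100% of optimal regions, so it was not used for ranking. The deposited summit offset, another position value the authors gave in bases from the region's start, placed each summit. Some regions shared coordinates with another region of the same list and differed in their summit (77 in the optimal list, 142 in the list of replicate 1), and all of them were kept.

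Read depth cannot be read from these lists, so the depth behind a signal is unknown. Exact Clopper-Pearson intervals (95%) on shares of regions and exact Poisson intervals on regions per Mb cover counting error over regions alone, and regions are not replicate samples. The dm6 lists were used throughout with the sequence of Release 6 of the genome and the gene models of Ensembl release 115 (BDGP 6.54). No dm6 region lay past the end of its chromosome arm in that sequence. The dm3 lists served only to repeat the counts, overlaps and signal ranks, and no coordinate was converted between builds.

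Replicates were compared on their N highest-signal regions, where N is the 6835 regions of the optimal list. Regions counted as shared when they overlapped by at least 1 bp. Chance overlap came from 100 placements of the regions at random positions on their own arms. The signal of an optimal region in a replicate was the highest signal among that replicate's overlapping regions. Spearman's rho across regions received an interval from bootstrap draws of regions. Summits were assigned, in this order, to a window of 500 bp around a transcription start site (TSS) of a protein-coding gene, 5′ UTR, coding sequence, 3′ UTR, other exon, intron or intergenic sequence. The comparison set, called other pooled regions here, was the 21689 regions of the pooled list that overlapped no optimal region, and shares were compared with a two-sided Fisher's exact test over regions.

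A protein-coding gene counted as bound when an optimal summit lay inside it or within 1 kb of it. Each of 19 gene lists was compared with 10000 random lists of protein-coding genes of the same size, matched on gene-length decile and excluding the list's own members. The permutation p was two-sided and adjusted over the 19 lists by the Benjamini-Hochberg procedure. The smallest p that 10000 random lists can give is 0.0002. In all, 21 list symbols had no match among the gene names used and were left out. Overlapping or neighbouring genes can share a region, and assignment by distance does not show which gene a region acts on. Random lists drew genes singly, so p can be too small for a list whose genes lie close together.

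Each of 20 consensus motifs was searched on both strands within 50 bp of each summit. The number of regions holding it was divided by the mean number in windows of the same width centred 300 bp to either side. An exact binomial test on regions with the motif in the summit window alone or in a randomly picked flank alone gave p, adjusted over the 20 motifs. The paired-domain, Motif 1 and CTCF consensus sequences were allowed 1 mismatch. A repeat of the motif test with flank windows matched on GC content was chosen after the base composition of the summits had been seen. For it, each of the 6835 summit windows was matched, without reuse, to 1 of 60000 flank windows of the pooled list with the same GC count, and the numbers were compared with Fisher's exact test. The same test on 6835 of those flank windows drawn without matching was added to separate the effect of GC content from that of the other flanks and test.

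The genes named in the report follow a rule set before the data were examined, as were the gene lists, the motifs, the tests and the alternatives not said to have been added. The rule takes the genes at the 20 highest-signal optimal regions found in the top-ranked lists of both replicates, assigned to the nearest protein-coding TSS within 5 kb. It adds every retinal determination gene, up to 4 bound members of each other list with the strongest regions, and the ey locus. Genes named for their number of regions in the closing observations fall outside it and were chosen after their values were seen. Alternatives were summits within 100 bp or a reciprocal overlap of 50% as the definition of a shared region, the 3417 optimal regions of highest signal, each replicate's top-ranked list alone, other TSS and gene windows, other matching of gene lists and other summit windows. The choices added after the data had been seen are named with their results.

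Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with Matplotlib 3.10.9. The procedures were tested on simulated data. With 79.8% of 6835 randomly placed regions copied at a 50 bp shift, the overlap step recovered 80.4%, which includes chance overlaps. Among simulated lists of 20 genes drawn from the 13945 protein-coding genes, the list test called 3.5% of those with no effect and 92% of those whose odds of being bound were raised 6 times. Those calls used an unadjusted p below 0.05, genes drawn singly and invented rates of binding per length decile. They do not give the power of the adjusted test, or that for lists of another size or of neighbouring genes. A paired-domain sequence planted at 100 of 6835 random summits raised the number of summit windows with the motif by 101.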

Results

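Eyeless is the fly Pax6 protein, a transcription factor with a paired domain and a homeodomain that is required for eye development and also acts in the brain. ChIP-seq, with an antibody against GFP per the labels' description and named ey in their antibody entry, mapped an ey-eGFP fusion in whole wandering larvae of the third larval instar, in 2 biological replicates numbered 1 and 3. The design answers where in the genome the fusion was found and how far the replicates gave the same regions. In dm6 the list of replicate 1 held 30000 regions with a median signal of 20.5 and that of replicate 3 held 27637 with a median of 18.3. The pooled list held 30000 regions and the optimal list 6835, with signals from 79.3 to 4342 and a median width of 430 bp. In dm3 the lists of replicate 1 and of the pool also held exactly 30000 regions. They may therefore have been cut at that number, on which the median signal of such a list would then depend. All 6835 optimal regions were also in the pooled list with the same position and signal, and they were exactly the 6835 pooled regions with the highest signal. No read totals accompany these lists, so the depth of the libraries is unknown.

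The strongest optimal regions lay at genes of varied function and were strong in both replicates. The highest signal of all, 4342, fell in an intron of ush (2L, 480563 to 481429), which encodes the zinc-finger cofactor U-shaped, 1365 bp from the TSS of cbt, the gene of the zinc-finger factor Cabut. This region ranked 1 in replicate 1 and 2 in replicate 3. The next were an intron of CG11050 (2L, 6612439 to 6612942, signal 3254), the promoter of CG14100 (3L, 19590381 to 19590860, signal 3220, 96 bp from the TSS) and that of Ugalt, a UDP-galactose transporter gene (X, 2703667 to 2704122, signal 2913, 28 bp from the TSS). CG1888 (signal 2889) and Lk6, a protein kinase gene (signal 2780), followed. Regions within 500 bp of a TSS were also found at ph-p, which encodes the Polycomb-group protein Polyhomeotic-proximal (signal 2640), Chro, which encodes the chromatin protein Chromator (2400.5), and PNPase, the gene of polynucleotide phosphorylase (2333). Further ones lay at larp (2315), gish, a casein kinase gene (2308), CenG1A (2244), Tcs5 (2194) and Sox14, an ecdysone-inducible Sox factor gene (signal 2184, 244 bp from the TSS). At Zw, the gene of glucose-6-phosphate dehydrogenase (signal 2382), and CG32772 (2314) the region was intronic. Of the 20 strongest, 4 had no protein-coding TSS within 5 kb. These were an intron of CG32486 (3L, 3060554 to 3061036), an intron of osa (3R, 17704190 to 17704685) and 2 intergenic regions (3R, 29214097 to 29214674, and X, 12752028 to 12752626). None of the 20 lay at a retinal determination gene.

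The replicates gave largely overlapping regions. Of the 6835 highest-signal regions of replicate 1, 5610 overlapped one of the 6835 highest-signal regions of replicate 3, which is 82.1% (95% exact interval 81.1 to 83.0). With regions placed at random on their arms the share was 3.66%, and at most 4.21% in 100 placements. In the other direction the share was 79.9%. The overlap was 79% among the top 100 regions, 80.7% among the top 1000 and 71.9% among the top 20000. It fell to 67.2% when regions had to overlap by 50% of both lengths. Of the optimal regions, 5474 (80.1%) overlapped a top-ranked region of both replicates, 611 of replicate 1 alone, 700 of replicate 3 alone, and 50 of neither.

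Strength was ordered alike in both replicates. Across the 6712 optimal regions that overlapped a region of each replicate, Spearman's rho of the signals was 0.779 (bootstrap interval 0.769 to 0.790) and Pearson's r of log2 signals was 0.829. These are correlations across regions of 1 pair of libraries, and regions are not independent replicates.

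**Figure D1:**
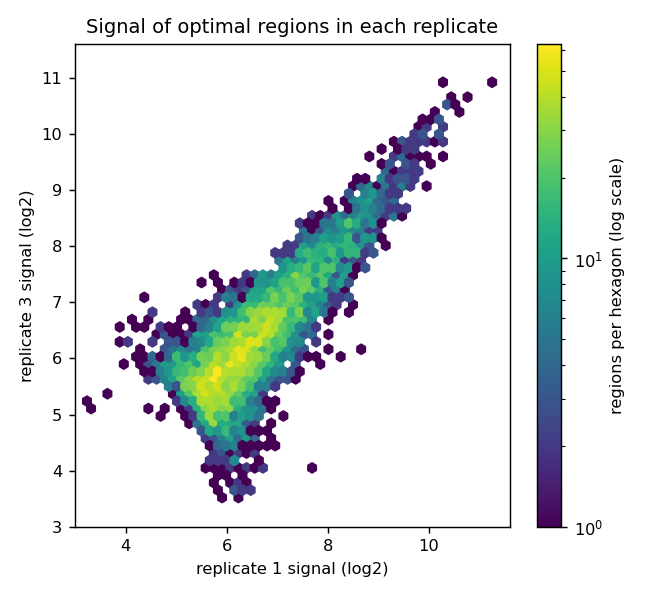
Signal of the 6712 optimal regions found in both replicate lists, as log2 of the authors' signal in replicate 1 (x axis) and in replicate 3 (y axis). Colour gives the number of regions per hexagon on a log scale, and signals rise together with a Spearman's rho of 0.779.

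Optimal summits gathered at promoters and were nearly missing from coding sequence. Of 6835 summits, 2673 (39.1%, 95% exact interval 37.9 to 40.3) lay within 500 bp of a protein-coding TSS, against 23.6% of the 21689 other pooled regions and 11.4% of randomly placed regions. Introns held 39.9% of optimal summits, against 44.0% of other pooled regions and 39.6% at random. For intergenic sequence the shares were 19.3%, 25.2% and 29.9%. Coding sequence farther than 500 bp from a TSS held 12 summits, 0.176%, against 3.76% of other pooled regions and 13.96% at random. For 3′ UTRs they were 0.892%, 2.38% and 4.50%, in the same order.

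The promoter share was 1.65 times that of the other pooled regions (Fisher's exact test over regions, two-sided, p = 1.03e-131). The ratio was 1.51 in the list of replicate 1 and 1.98 in that of replicate 3, so it lay above 1 in both. Of the 1367 strongest optimal regions, 44.7% had summits near a TSS (interval 42.0 to 47.4), against 35.7% of the 1367 weakest (interval 33.2 to 38.3). The p counts regions, which are not replicate samples.

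**Figure D2:**
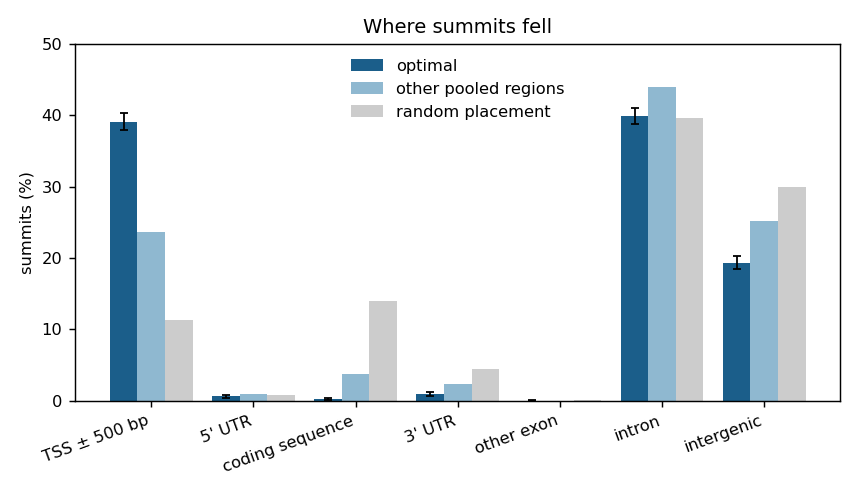
Share of summits (y axis, percent) in each annotation class (x axis) for optimal regions, other regions of the pooled list and regions placed at random on their arms, with 95% exact intervals on the optimal bars. Random shares are means of 10 placements. Optimal summits stand above random at promoters (39.1% against 11.3%) and below it in coding sequence (0.176% against 13.96%).

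Summits sat on short stretches of AT-rich DNA. Within 50 bp of optimal summits the mean GC content was 34.4% (SD 8.56 across regions, 6835 regions), and in windows 300 bp to either side it was 44.7%. GC content was lower in the summit window than in the flanks in 80.3% of regions, against 56.9% of other pooled regions and 47.9% of random positions. The same difference, summit minus flank, was −9.94 percentage points for the top-ranked regions of replicate 1 and −9.90 for those of replicate 3, but −2.78 for the other pooled regions and −0.0137 for random positions. It was −13.5 for the 1367 strongest optimal regions and −7.62 for the 1367 weakest. Within 400 bp of the summit the GC content of optimal regions was 41.8%, close to the 42.1% of random positions.

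**Figure D3:**
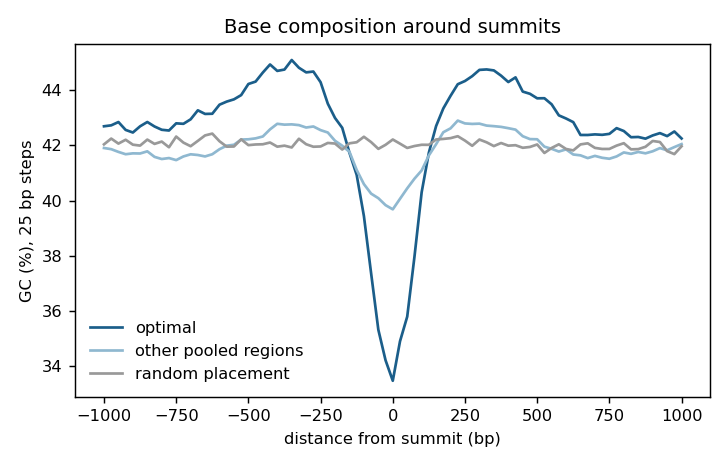
Mean GC content (y axis, percent, in steps of 25 bp) against distance from the summit (x axis, bp) for optimal regions, other pooled regions and random positions. The optimal curve dips at the summit, where the mean within 50 bp is 34.4%, and lies above the random curve about 300 bp away, where it averages 44.7%.

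Optimal regions were spread over the large chromosome arms and sparse on chromosome 4, the small dot chromosome that carries ey. They numbered 54.5 per Mb on X (95% exact Poisson interval 51.5 to 57.5), 53.3 on 2L, 47.1 on 2R, 53.1 on 3L and 49.8 on 3R. Chromosome 4 held 20 regions, or 14.8 per Mb (9.06 to 22.9), 0.292 times the density of the arms of 2 and 3 (interval 0.178 to 0.452). This ratio was 0.273 in the list of replicate 1 and 0.401 in that of replicate 3, and 0.766 for other pooled regions. For X the ratio to the arms of 2 and 3 was 1.07 (interval 1.01 to 1.14). It was 0.985 in the list of replicate 1 alone and 1.17 in that of replicate 3 alone, so a difference of X from the autosomes was not found in both replicates.

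Of the 14 retinal determination genes, which include the factors that act with and downstream of Eyeless in the eye primordium, 5 were bound. The strongest region was at hth, which encodes the homeodomain protein Homothorax, with 9 optimal regions in and around a gene of 132008 bp. Its best region (3R, 10579604 to 10579922, intron) had a signal of 305 and rank 1264. At so, the sine oculis gene, 1 region lay 247 bp from the TSS (2R, 7418888 to 7419317, signal 102.8, rank 5219). At dac, the dachshund gene, 2 regions were found, the stronger 543 bp from the TSS (2L, 16486326 to 16486755, signal 86.7, rank 6228). Optix had 1 intronic region (2R, 8035948 to 8036377, signal 83.0, rank 6535). Of these genes, hth and ey alone had a best region that was in the top-ranked lists of both replicates.

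The tagged gene itself had 1 region within 1 kb, 885 bp upstream of its TSS (4, 696589 to 697018, signal 181, rank 2679). A further 2 optimal regions lay farther upstream, at 695249 to 695375 (signal 255) and 695794 to 696223 (signal 105). Not bound were eya, which encodes the transcriptional coactivator and phosphatase Eyes absent, toy, the other fly Pax6 gene, and ato, eyg, toe, tsh, tio, dan and danr. No pooled region was found at ato or danr, in a list whose lowest signal was 15.4. At the others the strongest pooled region fell short of the optimal list, with a signal of 74.0 at eyg, 51.9 at eya, 47.1 at dan, 46.6 at tsh, 38.0 at toe, 36.8 at tio and 24.1 at toy. Random lists matched on gene length had a median of 7 bound genes, and 95% of them between 28.6% and 78.6% bound. The 35.7% of the retinal determination genes lay inside that range (permutation test, p = 0.339, adjusted p = 0.495).

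Across the genome 4749 of 13945 protein-coding genes (34.1%) were bound. Ribosomal protein genes and genes of the ecdysone response, the steroid programme of larval moults and metamorphosis, were bound more often than length-matched genes. Of 85 ribosomal protein genes, 60 (70.6%) were bound, against a median of 21 in random lists (adjusted permutation p = 0.0019). At RpL34b a region lay 99 bp from the TSS (rank 490), and at RpS20 189 bp (rank 624). The strongest regions by rank were near RpL31 (rank 88) and RpS19b (rank 230), at 1675 bp and 895 bp from their own TSSs. Of 23 ecdysone genes, 21 (91.3%) were bound, against a median of 13 (adjusted permutation p = 0.0038). Eip75B, a nuclear receptor gene, had 16 regions, the best an intronic one with rank 41 (3L, 18011640 to 18012138). Eip78C (rank 72) and Hr4 (rank 108), also nuclear receptor genes, and Eip63F-1 (rank 229) followed. Both excesses were found in either replicate's list, with 56 and 60 ribosomal protein genes and 21 and 20 ecdysone genes bound in replicates 1 and 3. When only regions within 1 kb of a TSS counted, 55 ribosomal protein genes but 11 ecdysone genes were bound, and the ecdysone excess was no longer past the threshold (adjusted permutation p = 0.497).

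Genes of neuronal function and of midgut digestion were bound less often than length-matched genes. Of 29 neuronal genes, 6 (20.7%) were bound, against a median of 17 (adjusted permutation p = 0.0019). They included elav, the pan-neuronal RNA-binding protein gene (2 regions, the best 268 bp from a TSS, rank 173), ChAT, the gene of choline acetyltransferase (rank 1241), Syx1A (rank 2859) and nSyb (rank 3956, 8058 bp from its own TSS). The nSyb region lay within 500 bp of another TSS and had no counterpart in the list of replicate 1. Without matching on gene length the deficit of neuronal genes was not past the threshold (adjusted permutation p = 0.376). Of 35 genes of midgut digestive enzymes 0 were bound, against a median of 8 (adjusted permutation p = 0.0038), with 2 bound in the list of replicate 1 (adjusted permutation p = 0.0669 without replicate 3) and 1 in that of replicate 3. Among the 3417 strongest optimal regions the adjusted permutation p of this list was 0.0752. Some of the midgut genes shared their strongest pooled region with another gene of the list, while random lists drew genes singly. The p-values of the midgut list can therefore be too small.

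For the other lists the share bound did not pass the adjusted threshold. Among 36 genes of eye patterning and signalling 20 were bound (random median 19, adjusted permutation p = 1, and 0.0365 as an excess without matching on gene length), led by aop, which encodes the ETS repressor Yan (9 regions, rank 272), N, the Notch receptor gene (3 regions, rank 295), spi, which encodes an EGF receptor ligand (7 regions, rank 386), and fng (rank 431). Among 28 genes of phototransduction 10 were bound (random median 12, adjusted permutation p = 0.763). They included norpA, the phospholipase C gene of the visual cascade, with an intronic region at rank 23 (X, 4324722 to 4325225, 1394 bp from a TSS), ninaG (rank 300), rdgA (rank 492, a region 49202 bp from its own TSS) and rdgC (rank 590). In the mushroom body list, a brain centre of learning, 13 of 23 were bound (adjusted permutation p = 1), among them dnc (rank 233), trio (rank 258), Syp (rank 670) and ab (rank 959). Of the medulla neuroblast temporal factors, to which ey itself belongs, 4 of 15 were bound (random median 7, adjusted permutation p = 0.281), namely hth, ey, Dll (rank 4557) and erm (rank 6728).

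Of 18 E(spl) and Notch pathway genes 11 were bound (random median 6, adjusted permutation p = 0.06), among them neur (rank 146), gro (rank 157), N and mam (9 regions, rank 297). The excess passed the threshold in 4 alternatives, with adjusted permutation p = 0.00665 in the list of replicate 1 alone, 0.0101 for the 3417 strongest optimal regions, 0.00912 with gene windows of 5 kb and 0.0365 with symbols matched through synonyms. Heat shock genes were bound in 9 of 18 cases (adjusted permutation p = 0.281), with Hsp27 at rank 49 and a region shared by Hsp26 and Hsp67Ba at rank 285, and Hsp83 at rank 816. Of 8 Hox genes 3 were bound (adjusted permutation p = 0.495), namely Antp (7 regions, rank 582), Ubx (4 regions, rank 3548) and lab (rank 4893).

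The lists for larval tissues gave no excess. The counts were 8 of 18 for fat body (Lsd-1, bmm, ppl and Adh at ranks 1461, 2033, 2592 and 2836), 6 of 23 for muscle (Msp300, Mlc2, Act87E and sls at ranks 83, 1235, 1373 and 1724) and 9 of 19 for glia (moody, Gs2, Ntan1 and loco at ranks 209, 311, 808 and 1350). They were 5 of 18 for haemocytes (ush, msn, PPO3 and lz at ranks 1, 411, 2961 and 3463), 3 of 16 for salivary glands (fkh at rank 684, Sgs5 and Sgs5bis sharing a region at rank 6077) and 3 of 24 for testis (topi, can and mia at ranks 1596, 3443 and 3994). The region at topi was shared with a ribosomal protein gene and lay 2914 bp from the TSS of topi. That at mia lay 2825 bp from its own TSS, and both lay within 500 bp of another TSS. The regions at Lsd-1, ppl and Mlc2 also lay within 500 bp of another TSS, at 3333, 1348 and 3697 bp from their own. For larval cuticle the count was 1 of 29 (Cpr49Ah, rank 5916, random median 6, adjusted permutation p = 0.0899). This deficit passed the threshold in 3 alternatives, with adjusted permutation p = 0.0019 both with gene windows of 5 kb and without matching on length, and 0.0471 with regions in both top-ranked lists. Some cuticle genes shared their strongest pooled region, while random lists drew genes singly, so the p-values of this list can be too small. The adjusted permutation p was 0.752 for fat body, 0.214 for muscle, 1 for glia and salivary glands, and 0.281 for haemocytes and testis.

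**Figure D4:**
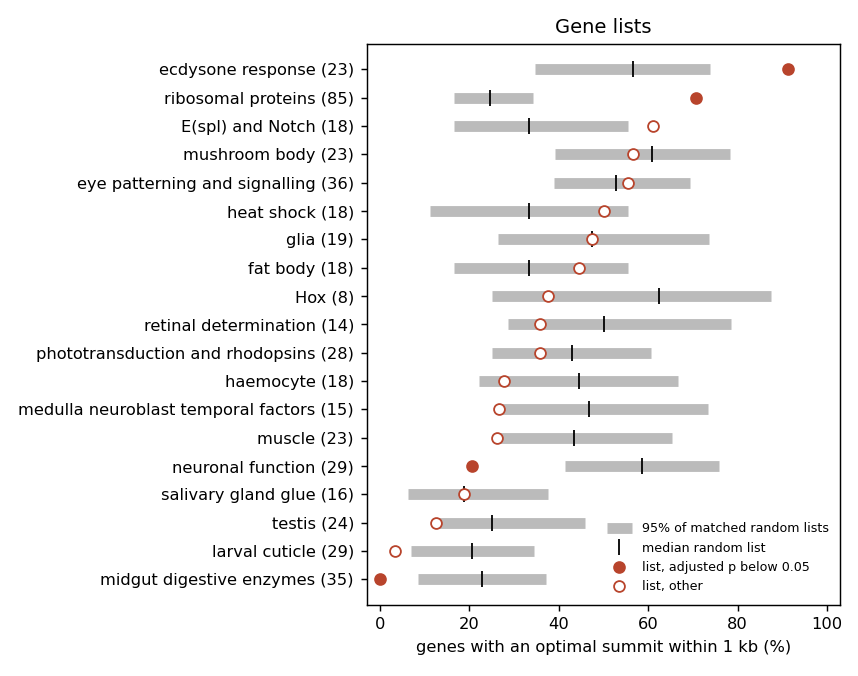
Share of genes with an optimal summit inside them or within 1 kb (x axis, percent) for each gene list (y axis, number of genes in parentheses), as circles that are filled where the adjusted p is below 0.05. Grey bars span 95% of random lists matched on gene length and ticks mark their median; ecdysone (91.3%) and ribosomal protein genes (70.6%) lie above their bars, neuronal (20.7%) and midgut genes (0%) below.

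The Pax6 paired-domain consensus TTCACGCWTSA was not enriched at summits. With 1 mismatch allowed it was found in 15 of 6835 summit windows and in a mean of 24.5 flank windows, a ratio of 0.612 (exact binomial test, adjusted p = 0.192). With no mismatch it was found in 0 summit windows and a mean of 0.5 flank windows. Against flanks matched on GC content the ratio was 0.652 (15 against 23 windows, adjusted exact p = 0.464).

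Among the 20 motifs, 7 were more frequent at summits than in the flanks. The DNA replication-related element DRE (TATCGATA), bound by DREF at promoters of housekeeping genes, showed the largest ratio, 4.65 (107 summit windows against 23, adjusted exact p = 3.62e-17). The others were the Pax6 homeodomain dimer site TAATNNNATTA (ratio 2.23), the Sine oculis site TGATAC (1.86), the homeodomain core TAATTA (1.73), the core promoter element Motif 1 (1.71), the Orthodenticle site TAATCC (1.57) and the E-box CATATG (1.29). Some were not particular to optimal regions. At summits of the other pooled regions DRE (2.62), Motif 1 (1.88), the Sine oculis site (1.36) and TAATTA (1.15) were also more frequent than in the flanks. The homeodomain dimer, TAATCC and CATATG did not pass the threshold there. Less frequent at summits were the GAGA factor site (0.353), CACGTG (0.467), CTCF (0.511), Zelda (0.535), CAGGTG (0.670) and CAGCTG (0.677). The GAGA ratio was 0.593 in the list of replicate 1 alone (126 summit windows) and 0.288 in that of replicate 3 alone (62 summit windows). The Zelda site did not pass the threshold in the 3417 strongest optimal regions (adjusted exact p = 0.0501) or within 25 bp of the summit (adjusted exact p = 0.118).

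Because summits and flanks differ in GC content, the test was repeated with GC-matched flanks, a choice made after the data had been seen. DRE (ratio 2.97, adjusted exact p = 1.87e-08), Motif 1 (2.56, adjusted exact p = 3.66e-10) and the Sine oculis site (1.33, adjusted exact p = 0.0206) stayed more frequent at summits. The homeodomain core (0.885, adjusted exact p = 0.095) and the homeodomain dimer site (0.936, adjusted exact p = 0.788) were then no longer more frequent, and neither TAATCC nor CATATG passed the threshold. The Sox site ACAAAG was less frequent (0.819, adjusted exact p = 0.00676). None of the 6 motifs that had been less frequent at summits passed the threshold, with ratios of 0.639 for Zelda (23 against 36 windows), 0.806 for CACGTG, 0.904 for GAGA, 1.15 for CTCF, 1.21 for CAGGTG and 1.23 for CAGCTG. Motif 1 did not pass the threshold in the 3417 strongest optimal regions against its own flanks (ratio 1.13, adjusted exact p = 0.971), nor within 25 bp of the summit (1.54, adjusted exact p = 0.123). CATATG lost it without replicate 1 (1.22, adjusted exact p = 0.0946).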

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

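The tests chosen after their result was seen are those of a diluted eye signal and of the short list for the retinal determination genes and those of region calling and of gene density for chromosome 4. The other tests in this part were fixed before their result was seen.

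Regions outside the 6 main chromosome arms appeared only in the dm3 lists and entered no comparison. There were 27 in the list of replicate 1, 59 in that of replicate 3 and 43 in the pooled list, on heterochromatic and unplaced sequence, and 1 of them on M in replicate 1. In the dm3 optimal list there was 1, on the heterochromatic sequence of 3L, with a signal of 128. The dm6 lists held 0.

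Optimal summits lay on AT-rich DNA, with GC content at the summit below that of the flanks. If promoter composition were the source, summits more than 500 bp from any TSS would lack the fall, but theirs was −11.6 percentage points against −8.39 near a TSS. Recognition of the homeodomain core TAATTA stays open. Against GC-matched flanks its ratio was 0.885 (95% interval 0.797 to 0.983). By the rule set before this result was seen, a ratio at or below 1 counted against such recognition. The ratio of 0.885 did not differ from 1 after adjustment over the motifs (Fisher's exact test, adjusted p = 0.095). The core holds only A and T, so matching on GC content also removes part of what its recognition would cause. Against the regions' own flanks the ratio was 1.73. It was 2.14 in the 3417 strongest optimal regions (338 against 158 windows), where the matched test was not run. The exact core lay in 8.79% of summit windows, while GC content fell in 80.3% of regions, against 47.9% of random positions. The exact core alone therefore cannot account for most of this excess over random positions. A preference of the libraries for AT-rich fragments stays open. Random positions with the GC content of optimal summits within 100 bp fell inside pooled regions 1.15 times as often as unmatched ones, but regions on AT-rich DNA would catch such positions whatever the cause, so this value decides nothing, and no biological explanation other than the homeodomain was tested.

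Retinal determination genes were not bound in excess, at 5 of 14. A short list could hide a small excess, but the exact upper limit of the bound share, 64.9%, lies below the 84.8% that an excess as large as that of the ecdysone genes would need. The ecdysone excess is an estimate from 23 genes and was taken as exact. When only regions within 1 kb of a TSS counted, it was smaller (47.8% against a random median of 34.8%), and the comparison was not repeated there. Dilution of eye cells in whole larvae could give the observed 35.7%. It cannot be told apart from a lack of excess in the eye cells themselves, because no list separates tissues.

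Chromosome 4 had few optimal regions for its length. Other pooled regions had 0.766 times the density of the arms of 2 and 3 (interval 0.654 to 0.891), against 0.292 for optimal regions (upper limit 0.452). This argues against a complete failure to call regions there. The other pooled regions are those below the signal of the optimal list, so a weaker signal on chromosome 4 would move regions into them. A partial deficit in calling is therefore not excluded. Fewer promoters may account for part of the difference. Of 80 protein-coding genes on chromosome 4, 12 had an optimal summit within 500 bp of a TSS, against 23.2% of genes on the arms of 2 and 3 (odds ratio 0.584, Fisher's exact test, p = 0.085). The density of genes was 0.554 times that of the other arms, above the upper limit for optimal regions but inside the interval of replicate 3 alone (0.401, interval 0.264 to 0.585), so gene number as the whole cause stays open, and no biological explanation was tested.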

How the results depend on the processing

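GC-matched and unmatched flanks of the pooled list, synonyms for list symbols and the restriction of gene lists to regions in both top-ranked lists were added after the data had been seen. The promoter ratio stayed between 1.46 and 1.98. The bound share of retinal determination genes ranged from 14.3% to 57.1% and never passed the threshold (lowest adjusted p 0.0798), nor did the paired-domain ratio, from 0 to 0.854. Requiring summits within 100 bp lowered the replicate overlap to 72.8%, the share of optimal regions in both top-ranked lists to 72.7% and the rank correlation to 0.753. A reciprocal overlap of 50% lowered them to 67.2%, 59.2% and 0.733. These definitions are stricter by construction. With the top 3417 regions of each replicate the share in both lists was 43.3%, since the optimal list stayed whole, and in the 3417 strongest optimal regions the correlation was 0.759. The X ratio was 0.985 to 1.17 with 1 replicate left out, so its direction turned without replicate 3, and the cause was not tested. With TSS windows of 1 kb, 1 gene list was bound in excess in place of 2. With GC-matched flanks, 3 motifs were enriched in place of 7, and among the motifs called at first the direction turned for the homeodomain dimer (0.936), TAATTA (0.885), CAGCTG (1.23), CAGGTG (1.21) and CTCF (1.15), none past the threshold. Flanks drawn from the same pooled list and tested the same way, but not matched on GC, left 7 enriched and turned none of the motifs called at first, so those changes came with the matching. Zelda lost its call there too (adjusted p 0.0738). Counting each setting, another list or motif lost the threshold in 15 cases and gained it in 14. Replicate overlap and correlation need both replicates and have no value without one. Read depth is unknown, and its effect on these results was not tested.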

Other observations

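The counts of regions per gene, the tests of other gene classes, of words of 6 bases and of GAGAGAG beside summits, and the GC-matched test were chosen after the data had been seen. The counts of GAGAGAG and DRE at summits and 300 bp away were planned.

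Among protein-coding genes, 1623 had at least 2 optimal summits inside or within 1 kb, 248 at least 5 and 41 at least 10. The highest numbers were at kirre, which encodes a cell adhesion protein of muscle founder cells (33 regions over 394149 bp), sbb (26 over 79099 bp) and shn, which encodes the Dpp pathway zinc-finger factor Schnurri (21 over 58309 bp). Next came CG1677, Ptp61F, a tyrosine phosphatase gene, and Tet, with 19 regions each, Tlk with 18 and Eip75B with 16. Among the genes with the most regions, Mnt, the gene of a Max-binding factor, had 4.71 regions per 10 kb and tara had 3.82, against 0.833 at kirre. Genes with fewer regions were not ranked per length.

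Among other gene classes, 8 of 32 snRNA genes (25%) had an optimal summit inside or within 500 bp, against 5.56% for genes placed at random on their arms. The highest of 100 placements gave 18.8% (permutation test, two-sided, adjusted p over 6 classes = 0.0297, which is the smallest that these placements gave). Genes were placed singly, so p can be too small for a class whose genes lie close together. For ncRNA genes the share was 14.5% against 8.68% (adjusted permutation p = 0.0297), and for pseudogenes 4.1% against 8.74% (adjusted permutation p = 0.0297). Protein-coding genes gave 30.8% against 18.6% (adjusted permutation p = 0.0297), so the excess was not particular to ncRNA genes. The shares for tRNA genes (7.59% against 4.98%, adjusted permutation p = 0.119) and snoRNA genes (5.95% against 5.16%, adjusted permutation p = 0.792) did not pass the threshold.

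The GAGA factor site GAGAGAG was more frequent beside summits than farther away. It was found in 1.1% of windows at the summit (75 regions, against 126 in the top-ranked list of replicate 1 and 62 in that of replicate 3), in 3.69% of windows 150 bp away, in 3.11% at 300 bp and in 1.61% at 2000 bp. Taking 1 side per region, 245 regions had it 150 bp away and not 2000 bp away, and 99 the reverse (exact binomial test, two-sided, p = 2.03e-15). DRE by contrast was found in 1.57% of windows at the summit, 1.05% at 150 bp and 0.337% at 300 bp. Mean GC content was 33.5% at the summit, 41.7% and 42.7% at 150 bp on its 2 sides, and 44.7% at 300 bp on both. At 1000 bp it was 42.7% and 42.3%, and at 2000 bp it was not computed. A lower frequency at the summit was not found against GC-matched flanks (75 against 83 windows, ratio 0.904, Fisher's exact test, adjusted p = 0.733), and the windows farther away were not matched. Among all 2080 words of 6 bases, 609 were more frequent at summits than in flanks and 1042 less frequent (exact binomial tests, Benjamini-Hochberg adjusted), and AT-rich words such as TTAAAA (2149 against 919 windows) led.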
